A study of Mus musculus with 18 samples.

How the data were processed

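RNA was sequenced from the epithelium of mammary buds 1 to 3 of mouse embryos. Per the labels' protocols, the ventral skin was treated with Dispase II and Pancreatin-Trypsin, and the epithelia were then dissected by hand under a microscope. Each sample pooled the tissue of 2 to 3 embryos that shared litter and genotype, and at least 3 litters were used. RNA was extracted with TRI Reagent and silica columns, and libraries were made with the Ovation SoLo RNA-seq kit, per the labels' protocols. The strain was a mix of C57Bl/6 and NMRI. The 18 libraries fell into 4 groups by embryonic day (E13.5 or E16.5) and genotype. Stabilized embryos carried Krt14Cre and 1 Ctnnb1 allele whose exon 3 is flanked by loxP sites, so that Cre removes this exon in the epithelium, and the protein made from that allele lacks the residues that mark β-catenin for destruction. Controls were littermates with the same allele and no Cre. There were 4 libraries per genotype at E13.5, from embryos of both sexes, and 5 per genotype at E16.5, from females alone, so stage and sex makeup cannot be separated.

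The submitters' processing notes name FastQC 0.11.8, MultiQC 1.9, Trimmomatic 0.39, Salmon 0.99.0 and DESeq2 3.15 (this last reads like the number of a Bioconductor release), with the build mm10, and give no settings. The main table holds deposited estimated counts per Ensembl gene; they were whole numbers in the file already, so no rounding was applied. The second table holds a deposited signal: each count divided by a factor that differed between genes within a library, as size factors combined with transcript lengths would give. It served only for 1 alternative, with the implied factors used as offsets. No value column of either table was left unused. A further deposit, a saved R object, was not read. The annotation release, the strand setting and the counter's settings are not given in the sources used here, so genes that overlap another gene, and families of near-identical members such as the hair keratins and keratin-associated proteins, have uncertain counts. Gene positions came from GENCODE mouse release M21 (GRCm38/mm10).

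The table held 24376 genes, 24166 of them with a symbol, and 38 identifiers shared their symbol with another identifier. Library totals ran from 26768810 to 36922108 counts. In edgeR 4.0.16 (R 4.3.3), filterByExpr with its default minimum count of 10 kept 17269 genes, TMM factors were computed, and a robust quasi-likelihood model with 1 mean per group was fitted to all 18 libraries (common dispersion 0.250). The comparisons were: stabilized minus control at E13.5, the same at E16.5, the difference between these effects (the interaction), and E16.5 minus E13.5 in controls and in stabilized samples. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. They measure the spread between pooled samples, not between single embryos. The litter of each library is not given, so libraries of a group or of both genotypes could share a litter, and the p-values treat them as independent. CPM, the library-scaled unit of edgeR, are counts relative to the TMM-scaled library total.

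Before the data were examined, 32 gene lists were written (704 members, 690 of them in the file): Wnt targets, Wnt ligands and receptors, embryonic mammary, luminal, basal and myoepithelial, epidermal differentiation, hair follicle placode, hair shaft and inner root sheath, Bmp and TGF-β, Fgf and MAPK, Hedgehog, Eda and NF-κB, Notch, cell cycle, cell-cycle inhibitors, steroid and PTH hormone signalling, adhesion and junctions, matrix remodelling, markers of mesenchyme, endothelium, immune cells, muscle, melanocytes, neural and Schwann cells, Merkel cells, adipocytes and erythroid cells, Y-linked genes, stress and immediate-early genes, interferon response, mitochondrially encoded genes and ribosomal proteins. Some genes stand in more than 1 list. Each list was compared with all other genes by camera (limma 3.58.1, log2 CPM with prior count 2, preset correlation 0.01, adjusted over the lists), again with an estimated correlation, and by fry, which asks whether the members move one way on balance and compares them with no other genes. Members past the threshold were counted over all genes and adjusted over the list alone. A score per library, the mean log2 CPM of the members, was compared between genotypes by exact two-sided permutation tests.

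Genes to be named were fixed by a rule written at the same time: always Ctnnb1, Krt14, Axin2 and Lef1; per genotype comparison the 6 genes per direction with the largest log2 fold change among those past the threshold, with a mean log2 CPM of at least 1 and no overlap between the groups; up to 3 members per list with the smallest adjusted p (1 for markers, sex, interferon, mitochondrial and ribosomal lists); 5 per direction for the stage effect in controls, and 4 per direction for the interaction, without predicted genes. List members that did not pass could be named with their values. List members that passed but lay outside the rule are named in places as examples, and these were chosen after their values were seen. Where 1 group had no counts, the fold is a lower bound against a floor of 3 counts over that group. With 1 to 3 counts, a 95% counting interval of the ratio is given. Intervals and floors cover counting error only, not the spread between libraries. The processing notes give no settings for duplicate reads.

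Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a filter of 10 CPM in 4 libraries, the offsets of the deposited signal, replicate number as a block, a term for sample numbers below 10, 1 surrogate variable (sva 3.50.0), a fit within each stage, a doubling or halving in addition to the threshold, a prior count of 0.5 for the scores, and leaving out each library in turn. A fit without 2 libraries that stood apart, and removal of 11 predicted genes made of satellite repeats, were added after the data were seen. The tests were also tried on simulated counts of the same depth and spread with 100 genes changed per fold size, in both directions. At a log2 change of 1, edgeR recovered 26 of 100 genes at E13.5, 54 at E16.5, 24 for the interaction, 39 for stage in controls and 35 for stage in stabilized samples. At a log2 change of 2 the numbers were 53, 69, 62, 67 and 55. False calls were 2 of 81, 3 of 126, 5 of 91, 2 of 108 and 1 of 91. A simulated shift of the Wnt targets by 1 was called by camera (adjusted p = 2.42e-40 at E13.5 and 1.84e-52 at E16.5), with 0 of 26 other lists. The simulated genes varied independently of each other. The 0 of 26 therefore cannot tell how often camera calls lists of genes that vary together. Other groupings of the real libraries, given at the end, had up to 12 lists called at E13.5 and 17 at E16.5.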

Results

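Transcripts were counted by RNA-seq in the epithelium of embryonic mouse mammary buds in which β-catenin, the effector of canonical Wnt signalling, was either stabilized (Krt14Cre with 1 Ctnnb1 allele that loses exon 3) or left as it was (Cre-negative littermates). There were 4 control and 4 stabilized libraries at E13.5, the bud stage, and 5 and 5 at E16.5, when the bud sprouts and begins to branch. Each library was a pool of embryos. At E13.5 the controls held 27417578 to 29310457 counts per library and the stabilized samples 26768810 to 27998587. At E16.5 the ranges were 27659003 to 36922108 and 29304083 to 36082518. The series states its aim as the role of Wnt/β-catenin signalling in the embryonic mammary gland. Errors of CPM (library-scaled counts) are SD with n = 4 at E13.5 and n = 5 at E16.5, errors of log2 fold changes are SE, and gene p-values are adjusted values from edgeR.

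**Figure D1:**
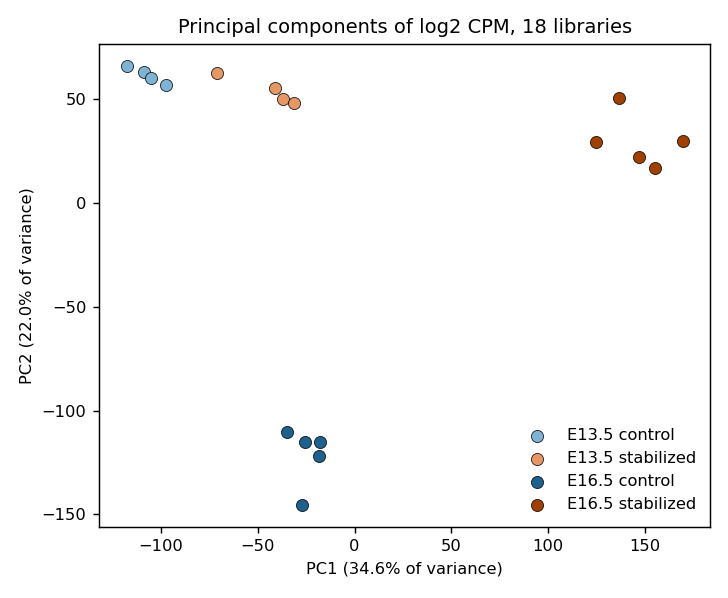
Principal components 1 and 2 of log2 CPM over the tested genes; each point is 1 of the 18 libraries, coloured by its group. The first axis held 34.6% of the variance and parts the E16.5 stabilized libraries (124.9 to 169.7) from all others (at most -17.9), and the second held 22.0% and parts the E16.5 controls (-145.4 to -110.3) from the other groups (at least 16.4).

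The targeted gene was measured in every library. Ctnnb1 (ENSMUSG00000006932, GRCm38/mm10 chromosome 9, 120929216 to 120960507) had 2683 ± 333 CPM in E13.5 controls and 3260 ± 347 CPM in E13.5 stabilized samples, a log2 fold change of 0.28 ± 0.165 that did not pass the test (edgeR adjusted p = 0.307). At E16.5 it had 1248 ± 111 CPM in controls and rose to 2278 ± 564 CPM in stabilized samples, by 0.87 ± 0.148 on the log2 scale (edgeR adjusted p = 9.02e-05). The deleted exon 3 (120950522 to 120950749, 228 bases) leaves the reading frame intact, and gene counts do not show its loss, so no share of recombined cells can be read from them. Krt14 (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548), the basal keratin whose promoter drives Cre, fell by 1.22 ± 0.247 on the log2 scale at E13.5, from 813 ± 104 to 349 ± 62.9 CPM (edgeR adjusted p = 0.00169). For Krt14, genotype effect at E16.5 was -0.37 ± 0.218 and did not pass (edgeR adjusted p = 0.189), but passed without stabilized replicate 1 (-0.69, edgeR adjusted p = 0.00234).

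The first comparison asked what differed between stabilized and control buds at E13.5. Controls carried no Cre, so at both stages effects of Cre or its insertion cannot be separated from those of stabilized β-catenin. Stabilized buds expressed some Hedgehog, Fgf and hair placode genes, such as Shh, Fgf4 and Lhx2, that control buds lacked or barely had. Nearly the whole cell-cycle list was higher. With an estimated correlation, camera kept the hair placode and cell-cycle calls and lost those of the Hedgehog list and of the Fgf and MAPK list. The embryonic mammary list split evenly, with Tbx3, Gata3 and Pthlh among the members that were lower. In edgeR, 1655 genes rose and 914 fell, 14.9% of those tested, and 1067 and 398 of them at least doubled or halved.

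The largest rises were in genes without a single count in the 4 controls. Fgf4 (ENSMUSG00000050917, chromosome 7, 144847367 to 144865243), which encodes a secreted growth factor, reached 92.9 ± 17.5 CPM, at least 3972.5-fold higher. Its neighbour Fgf3 (ENSMUSG00000031074, 144838083 to 144844436) reached 21.3 ± 5.14 CPM, at least 911-fold higher. Grin2c, a glutamate receptor subunit, rose to 26.3 ± 5.81 CPM, at least 1126-fold. The transcription factor genes Foxc1 (26.1 ± 13.1 CPM, at least 1115-fold) and Cdx1 (15.8 ± 6.73 CPM, at least 677-fold) and the adenylate kinase gene Ak5 (14.4 ± 2.90 CPM, at least 617-fold) completed the 6 largest. In the other direction, Unc13c, a regulator of vesicle release, fell from 8.61 ± 2.15 CPM to 0 counts, at least 341-fold lower, and Grm7 from 4.11 ± 3.34 CPM to 0 counts, at least 163-fold lower. Trhde fell by 5.77 on the log2 scale, Siah3 by 5.01, Bmper, a modulator of Bmp signalling, by 4.97, and the ephrin receptor gene Epha6 by 4.93.

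Of 13 Hedgehog genes, 6 rose and 2 fell (8 and 2 adjusted over the list alone, median log2 fold change 0.74). Camera called the list (adjusted p = 1.36e-06), though not with an estimated correlation (adjusted p = 0.0992 with an estimated correlation). Ptch1 (ENSMUSG00000021466, chromosome 13, 63508328 to 63573598), the Hedgehog receptor and itself a target of the pathway, rose from 33.9 ± 13.7 to 1003 ± 218 CPM (log2 fold change 4.89 ± 0.284, edgeR adjusted p = 8.17e-10). The ligand gene Shh (ENSMUSG00000002633, chromosome 5, 28456815 to 28467256) rose from 0.155 ± 0.291 to 141 ± 31.03 CPM, and the effector gene Gli1 from 1.23 ± 1.43 to 154 ± 16.46 CPM. Hhip, with 1 count in the controls, reached 12.3 ± 3.25 CPM, a ratio with a counting interval of 281 to 61942. The hair placode list shares Ptch1 with the Hedgehog list. It had 18 members up and 1 down of 28 (19 and 2 adjusted over the list alone, median 1.13). Its camera call held with an estimated correlation (adjusted p = 3.79e-11, and 0.00526 with the estimate). Lhx2 (ENSMUSG00000000247, chromosome 2, 38339281 to 38369733), a transcription factor of hair follicle precursors, rose from 0.388 ± 0.336 to 58.5 ± 18.9 CPM.

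The cell-cycle list moved as 1 block: 40 of 41 members rose and 0 fell (the same counts adjusted over the list alone), with a median log2 fold change of 1.30 (camera adjusted p = 1.15e-29, and 0.0307 with an estimated correlation). Ccne1, which encodes cyclin E1 of the step into DNA synthesis, rose from 6.97 ± 1.88 to 40.6 ± 4.96 CPM, the spindle checkpoint gene Bub1b from 24.7 ± 6.75 to 81.6 ± 12.8 CPM, and the cyclin gene Ccna2 from 26.6 ± 7.02 to 83.4 ± 13.4 CPM. Gins2 alone did not pass (0.31 ± 0.348, edgeR adjusted p = 0.662). Among 16 cell-cycle inhibitors 2 rose and 2 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.631). Without stabilized replicate 2, 5 rose. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), which encodes p21, rose from 10.2 ± 4.38 to 384 ± 111 CPM (log2 fold change 5.24 ± 0.338).

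Wnt targets moved unevenly at this stage. Of 25, 13 rose, 3 fell and 9 did not pass (14 and 4 adjusted over the list alone, median 0.58, or 0.61 with genes at 0 counts set to their bound, camera adjusted p = 6.18e-05, but adjusted p = 0.0887 with an estimated correlation). Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), a feedback inhibitor often used as a Wnt reporter, had 312 ± 53.6 and 424 ± 57.2 CPM, a change of 0.45 ± 0.174 that did not pass (edgeR adjusted p = 0.0976). Lef1 (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356), a nuclear partner of β-catenin, fell from 611 ± 124 to 331 ± 39.9 CPM (-0.88 ± 0.207, edgeR adjusted p = 0.00556). This call was lost with the offsets of the deposited signal. The other 2 that fell were Lgr5 (-1.36) and Znrf3 (-0.63). Bambi rose by 3.72, Prdm1 by 3.37 and Apcdd1 by 1.74 on the log2 scale. Among secreted Wnt antagonists, Dkk4 rose from 22.6 ± 29.3 to 471 ± 167 CPM and Notum from 63.2 ± 11.1 to 549 ± 130 CPM. Of 29 Wnt ligands and receptors, 6 rose and 4 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.533). They included the receptor genes Ror1 (2.05) and Ror2 (1.89), which rose, and the ligand gene Wnt5a (-1.26), which fell.

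Among other lists, camera called Fgf and MAPK, Bmp and TGF-β, and Notch genes upward, and Eda and NF-κB and interferon genes downward. All of these calls were lost with an estimated correlation. Fgf and MAPK genes rose in 13 of 28 cases and fell in 3 (14 and 4 adjusted over the list alone, median 0.46, camera adjusted p = 0.000219, and adjusted p = 0.0887 with an estimated correlation). Fgf9 stood at 2.31 and Dusp6, a feedback phosphatase, at 1.48. Bmp and TGF-β genes rose in 12 and fell in 3 of 28 (the same adjusted over the list alone, median 0.58, camera adjusted p = 0.000417, and adjusted p = 0.205 with an estimated correlation). Tgfb2 stood at 2.68 and Tgfb3 at 1.84. Notch genes rose in 8 and fell in 1 of 21 (8 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 0.00162, and adjusted p = 0.0887 with an estimated correlation). The Notch ligand gene Dll1 rose from 2.91 ± 1.58 to 26.02 ± 1.83 CPM, and the list members Heyl and Hes6 rose by 5.18 and 2.24. Eda and NF-κB genes (the Eda_NFkB list, E13.5) were called downward, with 3 up and 7 down of 24 (3 and 8 adjusted over the list alone, median -0.45, or -0.47 with bounds, camera adjusted p = 0.0201, and adjusted p = 0.407 with an estimated correlation), a call lost without control replicate 2 (adjusted p = 0.0686). Only 4 fell without control replicate 1 or 2 or stabilized replicate 1 or 4. Relb (-1.98), Icam1 (-1.73) and Tnfaip3 (-1.72) were among those that fell. Interferon genes fell in 4 and rose in 1 of 17 (7 and 1 adjusted over the list alone, median -0.58, or -0.59 with bounds, camera adjusted p = 0.015, and adjusted p = 0.0887 with an estimated correlation). Without control replicate 3, 7 interferon genes fell. Irf1 stood at -2.34.

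Of the embryonic mammary list, 10 of 31 members rose and 10 fell (12 and 10 adjusted over the list alone, median 0.27, mean -0.08, camera adjusted p = 0.875). Tbx3 (ENSMUSG00000018604, chromosome 5, 119670669 to 119684724), required for mammary bud formation, fell from 1330 ± 203 to 552 ± 45.1 CPM (edgeR adjusted p = 2.66e-06). The parathyroid-hormone-related protein gene Pthlh fell from 266 ± 34.2 to 99.3 ± 29.9 CPM and the transcription factor gene Gata3 from 1048 ± 179 to 397 ± 59.1 CPM. Sostdc1, an inhibitor of Wnt and Bmp signalling, rose from 46.1 ± 7.81 to 477 ± 105 CPM. Luminal genes showed 4 rises and 5 falls among 25 (4 and 6 adjusted over the list alone, median 0.05, mean 0.16, camera direction down, adjusted p = 0.877). The retinoic acid enzyme gene Aldh1a3 rose by 6.12 and Krt7 by 2.98, while the receptor gene Kit fell by 2.09. Of 20 steroid and PTH genes 3 rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.364). Igf2 rose by 1.74 and the vitamin D receptor gene Vdr fell by 1.56.

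Basal and myoepithelial genes rose in 12 and fell in 4 of 25 cases (15 and 5 adjusted over the list alone, mean 1.33, camera adjusted p = 0.00257, and adjusted p = 0.211 with an estimated correlation). The contractile genes Mylk (4.70) and Tagln (3.18) rose, Krt5 rose from 613 ± 106 to 1369 ± 355 CPM, and the integrin gene Itga6 fell from 784 ± 181 to 277 ± 62.6 CPM. Adhesion and junction genes rose in 8 and fell in 1 of 28 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00642, and adjusted p = 0.446 with an estimated correlation). The desmosomal genes Dsg3 (4.42) and Pkp1 (3.26) and the cadherin gene Cdh2 (3.47) rose. Hair shaft and inner root sheath genes (the Hair_shaft_IRS list, E13.5) rose in 13 and fell in 0 of 45 (16 and 0 adjusted over the list alone, median 1.11, or 1.40 with bounds, camera adjusted p = 0.0355, and adjusted p = 0.7 with an estimated correlation). This call was lost without control replicate 2 (adjusted p = 0.0842), control replicate 3 (0.103) or stabilized replicate 3 (0.115). Padi1 rose by 3.58 and Foxq1 by 1.80. Epidermal genes rose in 9 and fell in 0 of 49 (9 and 0 adjusted over the list alone, median 0.55, or 1.23 with bounds), without a camera call (adjusted p = 0.0654). Without stabilized replicate 2 the Epidermal_differentiation list, E13.5, was called (camera adjusted p = 0.018). Calm4 rose by 6.75 and the transcription factor gene Grhl1 by 1.66. Matrix genes rose in 8 and fell in 4 of 26 (8 and 4 adjusted over the list alone, camera adjusted p = 0.467). Lamc1 stood at 1.02, Mmp2 at -1.10 and Mmp11 at -1.19.

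Markers of other cell types gave no camera call at E13.5. Mesenchyme rose in 1 of 18 members, or 5 without control replicate 3 (1 adjusted over the list alone, median -0.02, mean 0.44, adjusted p = 0.631), endothelium in 1 of 11 (0, median 0.22, mean -0.05, direction down, 0.893), immune cells in 1 of 15 (1, 0.631), muscle in 1 of 13 (0, 0.411), neural and Schwann cells in 2 of 16 (3, 0.427) and melanocytes in 1 of 11, with 1 that fell (1 and 1, 0.511). Of 7 Merkel cell genes 2 rose and 1 fell (3 and 1, median 4.39, or 1.82 with bounds, 0.159): Isl1, absent from controls, reached 12.1 ± 6.97 CPM, at least 517-fold higher. Adipocyte (6), erythroid (2), Y-linked (4) and ribosomal protein (30) genes had 0 members past the threshold over all genes, with camera adjusted p of 0.56, 0.751, 0.5 and 0.875. Over the list alone 1 erythroid gene rose. Stress genes rose in 4 and fell in 0 of 22, or rose in 1 or 2 without control replicate 1 or 2 or stabilized replicate 1, 3 or 4 (4 and 0 adjusted over the list alone, 0.454), and 1 of 13 mitochondrially encoded genes fell (1 adjusted over the list alone, 0.174). Camera called the Ribosomal_protein list, E13.5, without control replicate 3 (adjusted p = 0.00548) and the Mitochondrial_encoded list, E13.5, without control replicate 2 (0.0497). The neuronal tubulin gene Tubb3 rose from 8.32 ± 2.14 to 183 ± 33.3 CPM. Control replicate 3 stood apart from its group, with 4.18% of counts from mitochondrial genes against 2.18 to 2.504% in the other 3 controls. Without it, together with 1 E16.5 library described with the second comparison, 3181 genes were called, 2312 of them the same.

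**Figure D2:**
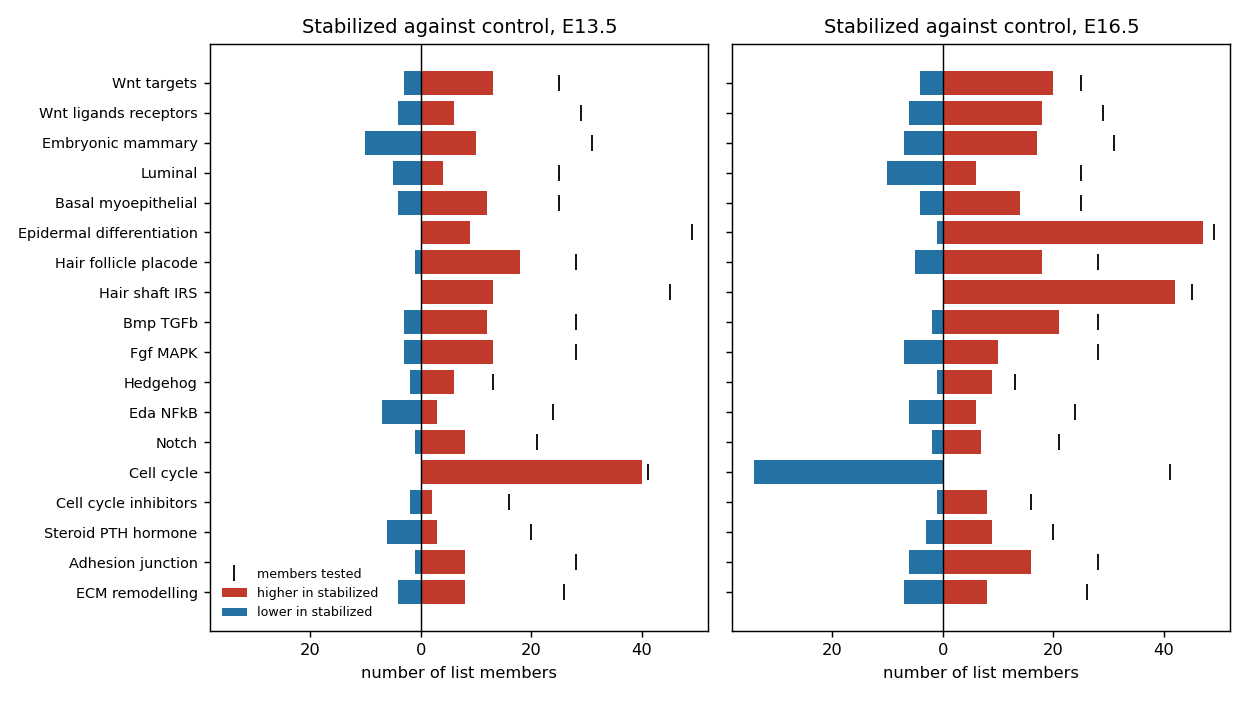
Number of members of 18 gene lists that were higher (bars to the right) or lower (bars to the left) in stabilized than in control samples, at E13.5 and E16.5, past an adjusted p of 0.05 in edgeR; ticks mark the members tested. The cell-cycle list had 40 members up at E13.5 and 34 down at E16.5, and the hair shaft list had 13 up at E13.5 and 42 up at E16.5.

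The E13.5 count was lower under some alternatives: 1712 genes passed with the offsets of the deposited signal and 1616 with a model of the 8 E13.5 libraries alone. In the scores per library, 17 of 32 lists reached 0.0286, the smallest exact permutation p that 4 against 4 can give, and 0 passed once adjusted (smallest adjusted p = 0.0538). Camera called 12 lists, 2 with an estimated correlation, and fry 16.

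The second comparison asked the same at E16.5, in the sprouting gland. Structural genes of the hair shaft that controls did not express were abundant in stabilized epithelium, epidermal differentiation genes rose almost without exception, and most members of the Wnt target, Bmp and Hedgehog lists rose, though with an estimated correlation camera kept only the hair shaft call of all these lists. Most genes of the cell-cycle list, whose call was also lost with an estimated correlation, and single genes such as Actg2, Krt8 and Sox10 were lower. In edgeR, 3838 genes rose and 3356 fell, 41.7% of those tested, and 2517 and 1072 at least doubled or halved.

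Hair shaft and inner root sheath genes rose in 42 of 45 cases and fell in 0 (43 and 0 adjusted over the list alone, median log2 fold change 10.61, or 10.17 with genes at 0 counts set to their bound), a call that held with an estimated correlation (camera adjusted p = 3.79e-32, and 0.00668 with the estimate). The keratin-associated protein genes Krtap16-1 (371 ± 153 CPM, at least 18488-fold higher), Krtap4-6 (216 ± 110 CPM, at least 10786-fold), Krtap6-1 (195 ± 57.5 CPM, at least 9736-fold) and Krtap1-4 (146 ± 83.5 CPM, at least 7271-fold) and the hair keratin gene Krt36 (153 ± 91.5 CPM, at least 7613-fold) had 0 counts in all 5 controls. Gprc5d, with 1 control count, reached 426 ± 121 CPM (counting interval of the ratio 11533 to 2538150), and Krt31, with 2 control counts, 474 ± 124 CPM (9792 to 292090). Krt81 (ENSMUSG00000067615, chromosome 15, 101459061 to 101463751) rose from 0.0446 ± 0.0844 to 1097 ± 286 CPM. How reads were split within these families is not known, so single members are less certain than the group. Krt79 (-0.62 ± 0.499), Foxq1 (0.33 ± 0.221) and Dlx4 (1.94) did not pass.

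Epidermal differentiation genes rose in 47 and fell in 1 of 49 cases (48 and 1 adjusted over the list alone, median 6.32, camera adjusted p = 4.41e-20, but adjusted p = 0.107 with an estimated correlation). The transcription factor gene Grhl1 rose from 24.3 ± 5.54 to 244 ± 88.1 CPM, the lipid barrier genes Cers3 from 12.7 ± 1.43 to 67.4 ± 36.1 CPM and Abca12 from 5.28 ± 2.06 to 172 ± 112 CPM. Plin2 fell by 0.85, and Flg2, with 0 counts in controls and 23.7 ± 45.9 CPM in stabilized samples, did not pass (edgeR adjusted p = 0.0502). The amounts differed widely between stabilized libraries: Krt10, the keratin of suprabasal epidermis, had 6963 CPM in replicate 1 against 288 to 652 CPM in the other 4, and 18.8 to 105.7 CPM in the controls. Adhesion and junction genes rose in 16 and fell in 6 of 28 (17 and 6 adjusted over the list alone, camera adjusted p = 0.0507). The desmosomal gene Dsp rose from 963 ± 116 to 7317 ± 3051 CPM and Cldn1 by 3.06. Camera called the Adhesion_junction list, E16.5, without control replicate 1 (adjusted p = 0.04), stabilized replicate 3 (0.0491) or stabilized replicate 4 (0.0187).

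Wnt targets now rose in 20 of 25 cases and fell in 4 (20 and 4 adjusted over the list alone, median 2.62, camera adjusted p = 1.61e-07, and adjusted p = 0.0643 with an estimated correlation). Axin2 rose from 27.9 ± 6.36 to 255 ± 42.0 CPM (3.19 ± 0.170, edgeR adjusted p = 2.85e-11) and Lef1 from 26.8 ± 7.02 to 165 ± 30.7 CPM (2.62 ± 0.196, edgeR adjusted p = 3.11e-09). Sp5 rose by 10.62, Notum by 7.31 and Apcdd1 by 3.54. The 4 that fell were Myc (-2.25), Ccnd1 (-2.08), Lgr5 (-1.76) and Nkd2 (-1.66). Wnt ligands and receptors rose in 18 and fell in 6 of 29 (18 and 6 adjusted over the list alone, median 1.59, camera adjusted p = 0.00335, and adjusted p = 0.295 with an estimated correlation). Among them were Wnt4 (3.81), Wnt10a (3.28) and Fzd1 (3.05).

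Bmp and TGF-β genes rose in 21 and fell in 2 of 28 (21 and 3 adjusted over the list alone, median 1.30, camera adjusted p = 1.24e-06, and adjusted p = 0.089 with an estimated correlation). Bmp4 rose from 1.45 ± 0.640 to 136 ± 18.02 CPM and Bmp2 from 3.93 ± 1.47 to 188 ± 31.2 CPM, while Id4 fell by 2.41. Hedgehog genes rose in 9 and fell in 1 of 13 (10 and 1 adjusted over the list alone, median 0.61, camera adjusted p = 0.000143, and adjusted p = 0.218 with an estimated correlation). Ptch1 rose from 35.8 ± 3.16 to 1081 ± 265 CPM and Shh from 0.222 ± 0.141 to 109.7 ± 24.6 CPM. Hair placode genes rose in 18 and fell in 5 of 28 (18 and 5 adjusted over the list alone, median 1.37, camera adjusted p = 0.000102, and adjusted p = 0.0649 with an estimated correlation). Lhx2 rose by 9.75 and Lmo4 fell by 1.35. Fgf and MAPK genes went both ways, 10 up and 7 down of 28 (10 and 9 adjusted over the list alone, median -0.11, mean 1.08, direction up, camera adjusted p = 0.715). Fgf20 rose by 4.85 and Fgfr3 by 3.45, and Etv5, a transcription factor induced by Fgf, fell from 528 ± 29.9 to 159 ± 34.4 CPM. Of 21 Notch genes 7 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.456). Jag1 rose by 1.82, and Dll1 (ENSMUSG00000014773, chromosome 17, 15367354 to 15376872) fell from 293 ± 25.9 to 19.4 ± 5.46 CPM. Eda and NF-κB genes rose in 6 and fell in 6 of 24 (6 and 6 adjusted over the list alone, camera adjusted p = 0.631). Tnfrsf19 stood at 1.04, Nfkb2 at -1.32 and Tnfaip3 at -1.27.

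The cell-cycle list was lower in stabilized than in control samples at this stage, with 0 of 41 members up and 34 down (0 and 37 adjusted over the list alone, median -0.87, camera adjusted p = 1.49e-12, but adjusted p = 0.135 with an estimated correlation). The DNA replication genes Mcm3 fell from 274 ± 20.1 to 106 ± 15.9 CPM, Rrm2 from 212 ± 29.2 to 93.9 ± 15.0 CPM and Mcm7 from 299.7 ± 39.4 to 144 ± 17.1 CPM. Mki67, a marker of cycling cells, did not pass (-0.36, edgeR adjusted p = 0.0901). Cell-cycle inhibitors rose in 8 and fell in 1 of 16 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0528). Gadd45g stood at 3.73, Cdkn1a at 3.19 and Cdkn1c at 1.98. Camera called the Cell_cycle_inhibitors list, E16.5, without control replicate 1 (adjusted p = 0.04), control replicate 3 (0.0467) or stabilized replicate 4 (0.037).

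Basal and myoepithelial genes (the Basal_myoepithelial list, E16.5) rose in 14 and fell in 4 of 25 cases (14 and 4 adjusted over the list alone, median 0.81, camera adjusted p = 0.0308, and adjusted p = 0.343 with an estimated correlation), a call lost without stabilized replicate 1 (adjusted p = 0.0514). Trp63 (ENSMUSG00000022510, chromosome 16, 25683763 to 25892102), the master regulator of stratified epithelia, rose from 92.1 ± 12.1 to 732 ± 41.2 CPM (2.99 ± 0.119, edgeR adjusted p = 1.41e-12), Lama3 by 2.65 and Dst by 2.37. Luminal genes fell in 10 and rose in 6 of 25 (10 and 7 adjusted over the list alone, median -0.23, camera adjusted p = 0.127). Krt8 fell from 245 ± 41.6 to 51.3 ± 28.3 CPM, Cldn7 by 2.20 and Tnfrsf11a, the receptor of RANKL, by 2.94. Krt7 rose by 5.43. The Embryonic_mammary list, E16.5, rose in 17 and fell in 7 of 31 (17 and 8 adjusted over the list alone, median 0.79, camera adjusted p = 0.0507, and adjusted p = 0.295 with an estimated correlation). Without control replicate 1 (adjusted p = 0.04), 2 (0.0387) or 3 (0.0427) or stabilized replicate 3 (0.0435) or 4 (0.0269), camera called it. Its members included the Hedgehog receptor gene Ptch1, given above, and Sox10, a transcription factor of mammary progenitors chosen here after its values were seen, which fell from 554 ± 59.0 to 29.6 ± 19.9 CPM.

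The largest falls lay outside most lists. Crispld2 (ENSMUSG00000031825, chromosome 8, 119992438 to 120052793), which encodes a secreted protein, fell from 246 ± 52.4 to 0.523 ± 0.372 CPM (-8.85 ± 0.535), the smooth muscle actin gene Actg2 from 45.9 ± 13.6 to 0.467 ± 0.303 CPM, and the transglutaminase gene Tgm2 from 45 ± 7.75 to 0.786 ± 0.361 CPM. Cytl1 fell by 5.42, Stk32b by 5.33 and the neuregulin receptor gene Erbb4 by 5.29. Matrix genes rose in 8 and fell in 7 of 26 (9 and 8 adjusted over the list alone, median 0.28, mean 0.15, direction down, camera adjusted p = 0.874). The basement membrane genes Col4a1 (-1.45), Col4a2 (-1.59) and Lama1 (-3.81) fell. Of 20 steroid and PTH genes 9 rose and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.183). Vdr rose by 2.63 and Igf2 from 312 to 1759 CPM.

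**Figure D3:**
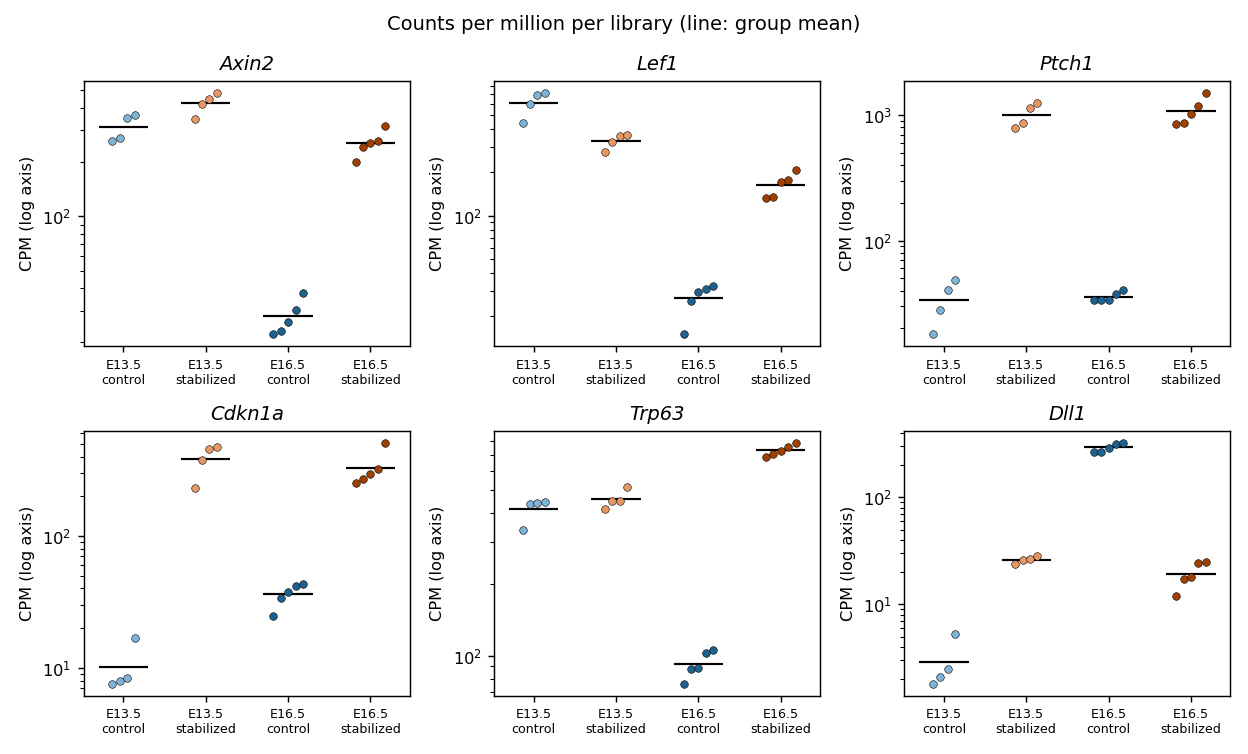
CPM (log axis) of Axin2, Lef1, Ptch1, Cdkn1a, Trp63 and Dll1 in each of the 18 libraries (points) by group, with a line at the group mean. Ptch1 was near 34 CPM in E13.5 controls and 36 CPM in E16.5 controls against 1003 and 1081 CPM in stabilized samples, and Dll1 was higher in stabilized samples at E13.5 (26.02 against 2.91 CPM) and lower at E16.5 (19.4 against 293 CPM).

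Markers of immune cells were called downward at E16.5 without a single member past the threshold (0 and 0 of 15, also adjusted over the list alone, median -1.31, camera adjusted p = 0.0138, and adjusted p = 0.0649 with an estimated correlation). The remaining marker lists gave no camera call: melanocytes 4 up and 0 down of 11 (4 and 0 adjusted over the list alone, adjusted p = 0.0711), Merkel cells 5 and 0 of 7 (5 and 0, 0.146), and adipocytes 2 and 0 of 6 (2 and 0, 0.187). The pigment enzyme gene Tyrp1 rose by 4.43 and Fabp4 by 6.45. In the scores per library, melanocytes (1.18), Merkel cells (1.91), adipocytes (1.55) and neural and Schwann cells (0.806) were higher in stabilized samples. Immune cells were lower (-1.55). Each of these passed the exact permutation test (adjusted p = 0.0141), and the scores of mesenchyme, endothelium, muscle and erythroid cells did not. Mesenchyme had 4 up and 3 down of 18 (4 and 3, median -0.40, mean 0.38, direction up, 0.86), endothelium 1 and 0 of 11 (1 and 0, median -0.32, mean 0.06, direction down, 0.875), muscle 1 and 1 of 13 (1 and 1, median -0.01, mean -0.27, direction up, 0.926), neural and Schwann cells 3 and 2 of 16 (3 and 2, 0.631), and erythroid cells 0 and 0 of 2 (0 and 0, median 0.41, direction down, 0.974). Stress genes rose in 5 and fell in 4 of 22 (5 and 4 adjusted over the list alone, 0.86). Hspb1 stood at 3.03 and Hsph1 at -0.96. Interferon genes had 0 up and 1 down of 17 (0 and 0, 0.86), mitochondrially encoded genes 2 and 0 of 13 (10 and 0, 0.119), ribosomal protein genes 0 and 1 of 30 (0 and 0, 0.495), and Y-linked genes 1 and 0 of 4 (1 and 0, median 0.01, or 1.40 with bounds, mean -0.13, 0.875). Camera called the Marker_melanocyte list, E16.5, without control replicate 1 (adjusted p = 0.04) or stabilized replicate 1 (0.0375), and the Mitochondrial_encoded list, E16.5, without stabilized replicate 3 (0.0114). The mitochondrial count depended on single libraries: 9 rose without stabilized replicate 3, 6 without control replicate 4 and 0 without control replicate 3, control replicate 5 or stabilized replicate 2. Leaving out an E13.5 control, which enters through the shared spread, gave 4 (replicate 1 or 2) or 8 (replicate 3), and without the last 5 ribosomal protein genes fell. Of the Merkel genes 3 rose without any of control replicates 1, 2, 3 and 4 or stabilized replicate 4. The Y-linked gene was Kdm5d (1.43), whose call was lost without stabilized replicate 4 (0.70). That replicate stood apart, with 24.01% of its counts on 11 predicted genes of satellite repeats against at most 0.810% elsewhere, 20719 genes with a count against at most 18540 in the other E16.5 stabilized libraries, and 98.9 CPM of the Y-linked gene Uty against 2.10 to 23.3 CPM in the other E16.5 libraries. The Y-linked genes Ddx3y and Eif2s3y together had 0 counts in it, against 1236 to 2414 in the E13.5 libraries. Without stabilized replicate 4 and E13.5 control replicate 3, 7217 genes were called at E16.5.

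With a doubling or halving required as well, 3589 genes passed at E16.5. Camera called 10 lists, 1 of them also with an estimated correlation, fry called 21, and the scores per library passed an adjusted exact permutation test for 21 lists.

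The third comparison asked whether the genotype effect differed between the stages. It did for 5562 genes, more positive at E16.5 for 2692 and more negative for 2870. Which side held more genes was not stable: it was the positive side with DESeq2 size factors (2875 and 2702), the DESeq2 test (3412 and 2945), the strict filter (2761 and 2384), the offsets of the deposited signal (2001 and 1891) and a doubling or halving required as well (1911 and 1761). The cell-cycle list was higher in stabilized than in control samples at E13.5 and lower at E16.5: 40 of 41 members had a negative interaction and 0 a positive one (the same adjusted over the list alone, median -2.16, camera adjusted p = 5.78e-26, but adjusted p = 0.0522 with an estimated correlation). Its mean score per library rose from 4.79 at E13.5 to 7.18 at E16.5 in controls. In stabilized samples it changed less, from 6.06 to 6.31. Hair shaft genes had 24 positive and 2 negative of 45 (25 and 2 adjusted over the list alone, median 8.43, camera adjusted p = 5.78e-26, and 0.0179 with the estimate). Epidermal genes had 17 and 0 of 49 (17 and 0, median 4.56, 1.62e-13, and adjusted p = 0.33 with an estimated correlation). Wnt targets had 14 and 5 of 25 (14 and 5, median 1.59, 0.000952, and adjusted p = 0.269 with an estimated correlation) and immune markers 0 and 3 of 15 (0 and 3, median -1.44, 0.0488, and adjusted p = 0.137 with an estimated correlation). Without E13.5 stabilized replicate 2, 1 immune marker had a negative interaction.

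By gene, the coefficient was 2.75 ± 0.238 for Axin2 (edgeR adjusted p = 8.32e-08), 3.50 ± 0.284 for Lef1 (edgeR adjusted p = 3.81e-08), 0.59 ± 0.221 for Ctnnb1 (edgeR adjusted p = 0.0487) and 0.85 ± 0.327 for Krt14 (edgeR adjusted p = 0.0541, not past). Shh and Gli1 showed no detectable difference (-0.77 ± 0.949, edgeR adjusted p = 0.589, and -0.54 ± 0.615, edgeR adjusted p = 0.552). The most negative coefficients were those of the potassium channel gene Kcnn4 (-13.01 ± 0.699), Fgf15 (-12.15 ± 1.14), the kinase gene Map3k21 (-12.05 ± 1.09) and the zinc transporter gene Slc30a2 (-11.48 ± 0.765). Each had at most 2 counts over the E13.5 controls, so the coefficients set no bound. Kcnn4, at 5.02 ± 1.14 CPM in E13.5 stabilized samples, had 116 ± 21.3 CPM in E16.5 controls and 5.91 ± 2.88 CPM in E16.5 stabilized samples. The most positive were Krtap16-1 (21.50 ± 3.22, lost without the 2 libraries that stood apart and with the sample-number term), Krt34 (18.99 ± 2.13), Krt33b (18.83 ± 1.95) and Krtap11-1 (18.75 ± 1.92), all with 0 counts in E13.5 stabilized samples. Several genes turned around, chosen here after their values were seen: Aldh1a3 (6.12 at E13.5, -2.43 at E16.5, interaction -8.55 ± 0.748), Dll1 (3.16 and -3.92) and Sox10 (2.62 and -4.22, interaction -6.84 ± 0.631) rose at E13.5 and fell at E16.5.

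Of the genes that rose at E13.5, 702 also rose at E16.5 where 367.8 would be shared by independent calls, and 502 fell where 321.6 would. Of those that fell at E13.5, 191 fell again (177.6) and 321 rose (203.1). With a doubling or halving required as well, 3672 genes kept an interaction call.

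**Figure D4:**
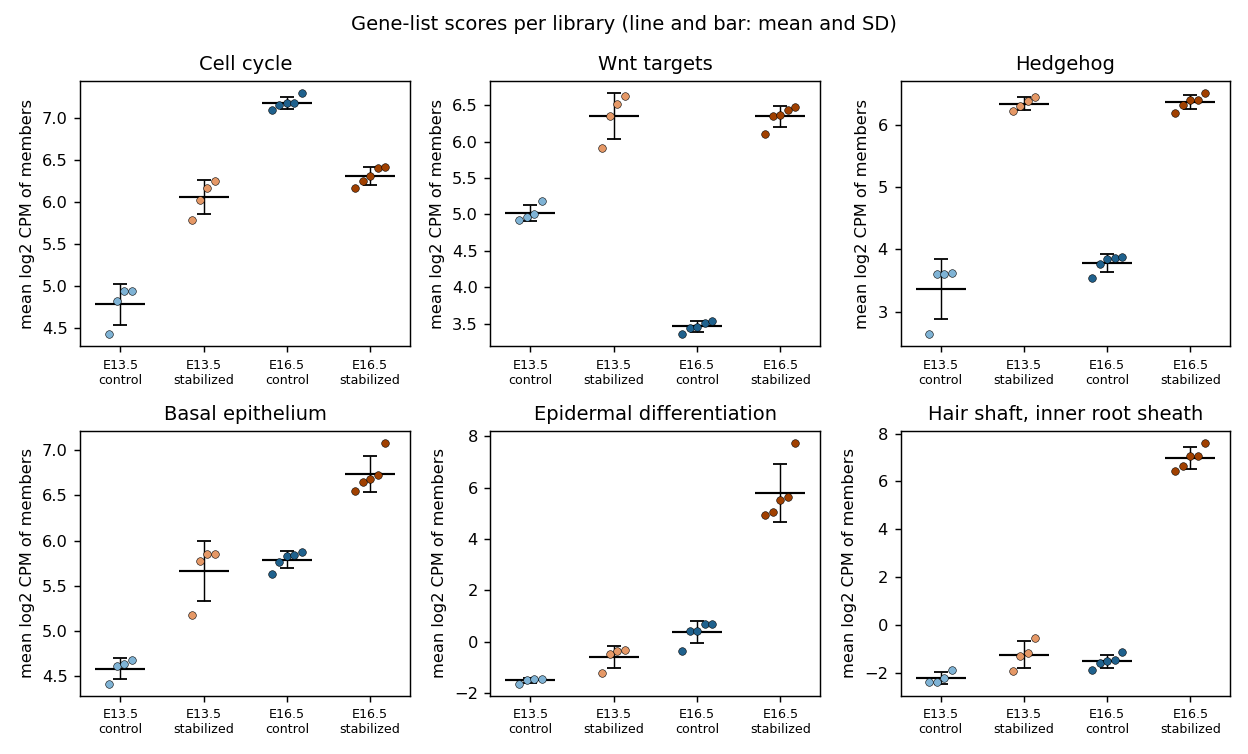
Mean log2 CPM of the members of 6 gene lists in each library (points), by group, with a line at the group mean and bars of 1 SD. The cell-cycle score was higher in stabilized than in control samples at E13.5 and lower at E16.5, and the epidermal score of E16.5 stabilized replicate 1 (7.74) stood above the other 4 (4.94 to 5.62).

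The last comparisons give the change between the stages in each genotype. E13.5 pools held both sexes and E16.5 pools females alone. In controls 4297 genes were higher and 3909 lower at E16.5, but with the strict filter more were lower (3267 and 3484). The cell-cycle list rose in 40 of 41 members and fell in 0 (40 and 0 adjusted over the list alone, median 2.39, camera adjusted p = 2.11e-25, and 0.0361 with an estimated correlation). The young bud had the lowest cell-cycle transcripts of the 4 groups. Wnt targets fell in 15 and rose in 6 of 25 (15 and 6, median -2.40, 0.000894, and adjusted p = 0.238 with an estimated correlation). Axin2 fell by 3.48 ± 0.176 and Lef1 by 4.51 ± 0.217. Wnt ligands and receptors fell in 14 and rose in 9 of 29 (14 and 9, 0.0472, and adjusted p = 0.598 with an estimated correlation). Luminal genes rose in 15 and fell in 5 of 25 (15 and 5, median 0.78, 0.0326, and adjusted p = 0.367 with an estimated correlation). Epidermal genes rose and fell in 20 and 0 of 49 (20 and 0, median 1.86, or 2.22 with bounds, 0.000894, and adjusted p = 0.683 with an estimated correlation). Adhesion genes did so in 13 and 5 of 28 (16 and 5, 0.0178, and adjusted p = 0.598 with an estimated correlation) and stress genes in 15 and 0 of 22 (16 and 0, median 1.78, 0.000173, and adjusted p = 0.598 with an estimated correlation).

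Markers of other cells moved with stage in controls. Immune markers rose in 11 and fell in 0 of 15 (11 and 0 adjusted over the list alone, median 4.59, or 4.28 with bounds, camera adjusted p = 0.000216, and 0.0165 with an estimated correlation). Melanocyte markers rose and fell in 8 and 0 of 11 (8 and 0, median 4.81, or 4.28 with bounds, 0.000325, a call lost at adjusted p = 0.05 with an estimated correlation), and Y-linked genes fell in 4 of 4 (4, median -6.80, 0.000173, and 0.0361 with an estimated correlation). The genes with the largest rises were Map3k21 (0 counts to 50.4 ± 4.03 CPM, at least 2153-fold), the iron-binding lipocalin gene Lcn2 (to 49.6 ± 27.2 CPM, at least 2119-fold), Cytl1 (to 47.2 ± 23.6 CPM, at least 2017-fold), Kcnn4 (ratio with a counting interval of 2661 to 585684) and Krt79 (3757 to 53251). The largest falls were those of Calb1 (11.4 ± 19.1 CPM to 0 counts, at least 570.2-fold lower, a call lost with replicate number as a block), Rnf112 (at least 462-fold lower), the Y-linked gene Eif2s3y (counting interval of the ratio 771 to 169870), Dkk4 (581 to 128105) and Hoxc5 (-10.55). With a doubling or halving required as well, 4652 genes passed.

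In stabilized samples 2852 genes were higher and 1990 lower at E16.5. Hair shaft genes rose in 42 of 45 (44 adjusted over the list alone, median 9.61, or 9.11 with bounds, camera adjusted p = 1.63e-42, and 0.00171 with an estimated correlation). Epidermal genes rose in 47 of 49 (48, median 8.32, or 7.28 with bounds, 9.78e-33, and 0.0367 with an estimated correlation). The cell-cycle list was not called, with 15 members up and 1 down (15 and 2 adjusted over the list alone, median 0.31, adjusted p = 0.104). Also called were melanocyte markers (9 up and 0 down of 11, 10 and 0, 3.72e-09, and 0.00323 with an estimated correlation) and Y-linked genes (0 and 3 of 4, 0 and 3, 5.36e-06, and 0.0106 with an estimated correlation). Stress genes (17 and 1 of 22, 20 and 1, 5.48e-06), mitochondrially encoded genes (10 and 0 of 13, 11 and 0, 8.52e-05), basal genes (12 and 1 of 25, 13 and 1, 0.00023), adhesion genes (17 and 4 of 28, 18 and 6, 0.002), Bmp and TGF-β genes (11 and 2 of 28, 11 and 2, 0.0156) and immune markers (5 and 0 of 15, 5 and 0, 0.0191) were called too. With an estimated correlation their adjusted p were 0.511, 0.511, 0.153, 0.511, 0.511 and 0.0695. With a doubling or halving required as well, 2393 genes passed.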

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

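The tests of satellite transcripts by genotype, of a lost Krt14 copy and of the hair genes in control-like epidermis were chosen only after the result was seen. Single samples are given here when they stood far from the other samples of their group. Chance alone sets about 1 in 20 groups apart in this way; 6 of 20 groups had such a sample for library measures, 11 of 128 for list scores and 27 of 439 for named genes.

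The genotype effect differed between the stages for 5562 genes, 108 of them named, and for 5 lists by camera: hair shaft genes and the cell cycle (adjusted p = 5.78e-26 each), epidermal genes (1.62e-13), Wnt targets (0.000952) and immune markers (0.0488). With an estimated correlation the hair shaft call held (adjusted p = 0.0179), and those of the cell cycle (0.0522), epidermal genes (0.33), Wnt targets (0.269) and immune markers (0.137) were lost.

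E16.5 stabilized replicate 4 had a count for 20719 genes (20720 to 4 digits), and 24.01% of its counts lay on 11 predicted genes of satellite repeats. Smaller satellite shares also stood apart in E13.5 stabilized replicate 2 (0.8101%), E16.5 control replicate 4 (0.2835%) and, on the low side, E13.5 control replicate 1 (0.0196%). Named genes in E16.5 stabilized replicate 4 were low on the log2 CPM scale for Ror2 (4.857), Bmp2 (7.083), Col4a1 (7.741), Col5a1 (7.891) and Sp5 (4.71). A rise of satellite transcripts shared by all E16.5 stabilized libraries is excluded. The highest share of the other 4 was 0.0899% and lay within the controls (0.0226 to 0.283%). An effect of genotype that reaches only some libraries cannot be excluded in this way. Genomic DNA carried into the library may add to the satellite share of replicate 4. There 86.8% of 681 olfactory and vomeronasal receptor genes had a count, against 48.6 to 65.8% in the other 17 libraries. This was 1.32 times the highest, short of the 1.5 times set in advance. That bound lay near the most a share can reach, so falling short of it says little against genomic DNA. The summed CPM of the receptor genes, looked at afterwards, was 3851 against at most 1820.5 in the other 9 E16.5 libraries but up to 3914 at E13.5, so genomic DNA cannot be told apart from a wider set of transcripts. No other biological explanation was tested.

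E13.5 control replicate 3 had 4.178% of its counts from mitochondrial genes. Its list scores stood apart for Hedgehog (2.64) and melanocytes (-1.193), and its log2 CPM for Bmp4 (6.798), Col4a1 (8.112), Lama1 (7.349), mt-Nd4 (12.03), Nfkb2 (4.18) and Trp63 (8.401). E16.5 stabilized replicate 1 was high in the epidermal score (7.744) and the stress score (7.513), in Cldn1 (7.847) and Dsp (13.63), and low in Fgf4 (2.147) and Map3k21 (1.168). E13.5 stabilized replicate 2 was low in the basal score (5.175), the epidermal score (-1.23), Ccna2 (5.993), Foxc1 (2.868) and Map3k21 (-0.9133) and high in Lama1 (7.62). The remaining list scores were epidermal in E16.5 control replicate 1 (-0.3497), steroid and PTH in E13.5 stabilized replicate 4 (3.936), muscle in E16.5 control replicate 5 (0.9556) and E16.5 stabilized replicate 2 (-0.9796), and mitochondrial in E16.5 stabilized replicate 3 (10.07). The remaining genes were Cdkn1a (4.067), Foxq1 (2.2) and Mmp2 (7.729) in E13.5 control replicate 4, Heyl in E16.5 control replicate 5 (1.834), Abca12 (0.9948) and Krt79 (6.763) in E16.5 control replicate 1, Unc13c in E16.5 stabilized replicate 5 (1.989) and Krtap16-1 in E16.5 stabilized replicate 3 (6.739).

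Krt14 fell at E13.5 while Krt5, its partner keratin, rose. A Krt14 copy lost to the Cre insertion would lower Krt14 by 1 on the log2 scale. The change was -1.22 ± 0.247 (SE) at E13.5, within 2 SE of that, and -0.37 ± 0.218 at E16.5, outside it. For Krt14, genotype effect at E16.5 was -0.69 without stabilized replicate 1, nearer to a lost copy. A lost copy thus cannot be told apart from regulation of Krt14. The log2 ratio of Krt14 to Krt5, used earlier for this test, changed by -2.36 ± 0.270 and -2.93 ± 0.185, but Krt5 itself rose, so the ratio decides nothing about Krt14. Reads of Krt14 assigned to Krt16 or Krt17 stay open, since the summed CPM of the 3 genes was 675.6 ± 122 (525 to 802) in stabilized and 840 ± 116 (742 to 1005) in control libraries. A change of Krt14 transcription in the stabilized epithelium stays open as well and was not tested apart from these.

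Epidermal and hair genes were high in all 5 E16.5 stabilized libraries, with 4752 to 37340 CPM over the epidermal list against 381 to 644 in controls and 10175 to 22026 CPM over the hair list against 233 to 488. Over the 42 hair genes that rose, the control level was set against the stabilized level per epidermal CPM. The ratio had a median of at most 0.00285 in the controls, and 29 genes lay under 0.1 in all 5 controls. Most of these genes thus had far less transcript per epidermal CPM in controls. The epidermal CPM of controls may come from the bud itself, and no control skin was analysed. The test therefore cannot exclude control-like epidermis carried along in dissection. This test replaced one that had been written earlier, after that one was seen. The earlier one compared summed hair per epidermal CPM, where the highest control (0.820) over the lowest stabilized library (0.590) gave 1.39 and met its bound for a cause; Krt79 (66.1%) and Dsc2 (15.0%) made up most of the control sum. Epidermis of mutant skin cannot be told apart from a change in the mammary epithelium itself, because no skin library was analysed; the stabilized libraries differed 7.86-fold in epidermal CPM, through replicate 1 (37340 CPM, against 4752 to 6300.4 in the other 4).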

How the results depend on the processing

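The fit without the 2 libraries that stood apart and the removal of 11 satellite genes were tests chosen only after the result was seen. No named gene or list past its threshold reversed its direction under the alternatives run. The side with more genes did turn for the interaction (2692 up and 2870 down) with DESeq2 size factors, the DESeq2 test, the strict filter, the offsets of the deposited signal and the required doubling or halving, and for stage in controls (4297 and 3909) with the strict filter (3267 and 3484). Requiring a doubling or halving as well, a stricter threshold by construction, left 1465 genes at E13.5, 3589 at E16.5, 3672 for the interaction, 4652 for stage in controls and 2393 for stage in stabilized samples. At E13.5 the offsets of the deposited signal gave 1712 genes (the cause was not tested), and a fit over the E13.5 groups alone gave 1616. A fit over the E16.5 groups alone, also with fewer samples to estimate the spread, gave 7964 against 7194 in the main fit. The fits of single stages thus moved in opposite directions, so fewer samples need not be the reason for the lower E13.5 count. That reason was not tested. Camera with an estimated correlation called 2 lists at E13.5 and 1 at E16.5, and fry, which compares with no other genes, called 21 at E16.5. The other alternatives kept the gene counts within 1.5 times, but the genes behind them could differ. With the term for sample numbers below 10, 2362 genes were called at E13.5, and 1737 of them were among the 2569 of the main fit. At E13.5 only controls had such numbers, so this term partly coincides with genotype. Leaving out each library in turn gave 1949 to 3051 genes at E13.5, 6432 to 7016 at E16.5, 4974 to 6104 for the interaction, 7426 to 8371 for stage in controls and 3996 to 4899 for stage in stabilized samples, and 11 to 13 lists at E13.5 and 10 to 14 at E16.5. Without the 2 libraries the counts were 3181, 7217, 6016, 8524 and 5534, and without the satellite genes 2588 at E13.5, 7196 at E16.5 and 5566 for the interaction. Replicate number as a block gave 2219, 6779, 5040, 7801 and 4468, and with it camera lost the Hair_shaft_IRS list, E13.5 (adjusted p = 0.0624), and the Basal_myoepithelial list, E16.5 (0.0704). Libraries of equal number correlated at -0.0995 to 0.172 once group means were removed, and most stabilized libraries correlated best with a control of another number, so the numbers were not used as pairs. Over the named genes 3412 values stayed as they were, called or not called, 88 lost their call and 1 gained it. Most named genes were picked for large or clear changes in these data, so this says little about other genes. For single lists 300 kept their call, 27 lost it and 40 gained it. Genes shared in direction between the stages numbered 893, against 1080 with DESeq2, 806 with the strict filter and 975 without the 2 libraries.

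Other groupings of the same libraries tested whether chance can give as many calls. Chance is unlikely for genes at E13.5 (2569 against at most 1492 in the other 34 of 35 splits, with 1 split as large, the real one). It is also unlikely at E16.5 (7194 against 5), for stage in controls (8206 against 5220) and for stage in stabilized samples (4842 against 2717), each from 100 splits. To be the largest of 35 is the most that the E13.5 splits can show, so they do not exclude chance. Libraries may also share litters, so the splits need not be interchangeable. For the interaction, 5562 genes stood against at most 752 in the other splits of 100. Those splits regrouped the genotypes within each stage, which removes the genotype effect itself. They cannot tell whether chance makes that effect differ between the stages. Chance cannot be excluded for the number of lists, where 3 of 35 splits at E13.5 (12 lists, highest other 12) and 35 of 100 at E16.5 (10 lists, highest other 17) gave as many.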

Other observations

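The tests of neighbouring genes among those that fell at E13.5 and those called at E16.5 were chosen only after the result was seen for genes that rose at E13.5, and the genes in the opening paragraph were picked after their values were seen. Sp6 rose at E13.5 from 37.2 ± 5.42 to 190 ± 45.1 CPM and at E16.5 from 2.46 ± 1.06 to 238 ± 78.1 CPM, and Hoxc13, a regulator of hair keratins, rose from 1.68 ± 1.35 to 11.1 ± 8.94 CPM and from 0.579 ± 0.371 to 93.8 ± 23.1 CPM. Msx2 rose from 19.5 ± 3.22 to 50.1 ± 32.8 CPM at E13.5 (edgeR adjusted p = 0.0233) and from 3.43 ± 0.687 to 146 ± 22.5 CPM at E16.5. Irx1 fell at both stages (-3.72 and -4.39), with no detectable difference between them in edgeR (interaction -0.67, adjusted p = 0.701).

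Fgf3, Fgf4 and Fgf15 are neighbours on chromosome 7 and rose together at E13.5, which raised the question whether risen genes lie side by side. Among 17160 tested genes with a location, 277 neighbouring pairs rose together, against a median of 159 and a maximum of 200 in 10000 shuffles of the calls (permutation p = 1e-04, the smallest they can give). Without pairs whose symbols match once the closing number and letters are removed, the number was 241 against 146. Family members with other symbols stayed in, and neighbours that overlap, whose counts are uncertain, were not set aside. Numbers also lay above the shuffle medians for genes that fell at E13.5 (90 against 49) and for those that rose (1228 against 847) or fell (822 against 655) at E16.5, so beside the 277 pairs neighbouring genes may respond together in either direction, which is not particular to this locus.

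Cell-cycle genes were high in E13.5 stabilized samples and in E16.5 controls, so stabilized buds might be advanced in stage. With the 4 E13.5 controls divided so that no library served both comparisons, and the cell-cycle list left out, genes that rose with stage in controls had a median E13.5 genotype log2 fold change of 0.22 to 0.341 over the 6 splits. Genes that fell with stage had -0.305 to -0.157, on the same side of 0 in all splits but not past the -0.2 set in advance in all of them. An advance in stage cannot be told apart from a separate effect on genes that also change with stage.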
